A study of Mus musculus with 12 samples.

How the data were processed

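RNA had been isolated from peritoneal macrophages of female mice with a Qiagen RNeasy mini kit, and sequencing libraries had been made with the NuGen Ovation Universal kit, per the labels' protocols. The authors' processing ran CASAVA 1.8.2 and STAR 2.5.2b, an aligner that splits reads across introns, against mm10, per the submitters' processing notes. The read counter, its annotation and whether it used strand are not given in the sources used here, so reads of genes that overlap on opposite strands cannot be told apart. The deposited table holds raw counts, whole and without normalization, for 35745 RefSeq transcript identifiers in 12 columns, each matched to a library by its name in the labels. A read shared by isoforms of a gene appears once in each isoform's count: among 3587 genes with several identifiers and a highest mean of at least 50 counts, the median ratio of the lowest to the highest mean was 0.935. Adding isoforms would therefore count reads several times, and each gene was represented by its transcript with the highest mean count over all libraries.

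Symbols came from a RefSeq gene table for 35440 identifiers and from the GENCODE RefSeq table for 188. The 117 identifiers without a symbol were kept under their identifiers and are counted as genes below. They entered library totals and, where they passed the filter, the tests. With 1 transcript per gene, they held between 2.33% (chow 24 h replicate 3) and 12.02% (HFD 0 h replicate 3) of a library's total, most of it in 1 identifier. The resulting 24558 genes, 6092 of them with more than 1 transcript, gave totals of 2360209 to 20688063 counts per library. Gene positions are those of the named transcripts in the RefSeq annotation of GRCm38.p6, the assembly behind mm10. In the shallowest library 3 counts equal 1.271 CPM and in the deepest 0.145, and folds, floors and intervals made from counts cover counting error only.

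Groups came from the diet and LPS time in the labels, with 3 libraries each. The labels do not say whether the libraries of a group come from separate animals, so p-values measure only the spread between these samples, which may be technical. Counts of library pairs within a group differed by more than sampling noise in a chi-square test over genes, so all 12 libraries were kept as separate replicates. CPM, the counts relative to the library total, used totals scaled by TMM. Genes were filtered with filterByExpr by group, which left 12638, and tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit with robust estimation and glmQLFTest) in 1 model of 4 group means over all 12 libraries, with Benjamini-Hochberg adjustment at 0.05. The common biological coefficient of variation was 18%. The SE of a log2 fold change was its absolute value over the square root of the F statistic of glmQLFTest, so it is not independent of the p-value. Contrasts were 24 h against 0 h within each diet, HFD against chow at each time, and the interaction. An increase or decrease is named as such only where it passed. A fold against a group at 0 counts is given as a bound against 3 counts over the group, and for 1 to 3 counts as a ratio with its exact 95% interval.

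Gene lists (34, with 829 entries, 806 of them matched) were fixed before the data were examined, as were 18 key genes, the rule for named genes and the alternatives, apart from those said to be added. Lists with at least 3 tested members, 32 of them, were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, adjusted over the lists. Erythroid markers had 0 tested genes, and the mitochondrially encoded genes were not analysed here. Camera with an estimated correlation and fry were run beside it. The rule named, for each comparison, the key genes, the 5 largest increases and 5 largest decreases among genes that passed with an official symbol, a mean of at least 10 CPM in the higher group and no overlap between the groups, and up to 4 members with the smallest adjusted p from a list described. Oasl2 and Ly6e at 0 h were named outside it, and a few genes that it names are not reported here.

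Alternatives were size factors by median ratio and by upper quartile, no filter and a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, only the libraries of the groups compared, a block (the number in the labels for LPS and the interaction, and the replicate number 1 to 3 for diet, where the label numbers are nested in diet, or the label number as a random effect), the lane tag as a covariate, a test for a change above 1.5-fold with glmTreat, and each library left out in turn. Only HFD 24 h holds libraries both with and without the lane tag, and only its replicate 1 carries it. With the tag fitted, diet at 24 h thus compares HFD 24 h replicate 1 alone with the chow 24 h libraries. The interaction takes its 24 h part from the same comparison. After the data were seen, isoform sums, limma-voom with sample quality weights, both chow replicate 1 libraries left out, and the GC slope of each library as a covariate were added. The functions that fit the models were tested on simulated counts with 200 changed genes per comparison, 50 at each of 4 fold sizes: at 2-fold they recovered 84% for LPS in chow, 82% for LPS in HFD, 74% for diet at 0 h, 78% for diet at 24 h and 44% for the interaction. The changed genes were drawn from those above a minimum mean level. Counts were simulated independently between genes, without the structure that genes of a library share, so recovery in the real libraries may be lower. Tables were joined with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.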

Results

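RNA was sequenced from peritoneal macrophages, phagocytes of the abdominal cavity, of female mice fed chow or a high fat diet (HFD). The cells had been exposed for 0 h or 24 h to lipopolysaccharide (LPS), a bacterial cell wall component that Toll-like receptor 4 recognises. The 12 libraries form 4 groups of 3: chow 0 h, chow 24 h, HFD 0 h and HFD 24 h. The labels name no group kept for 24 h without LPS, so LPS and the time that passed with it cannot be told apart. Changes from 0 h to 24 h are called LPS changes below. Counts summed over 1 transcript per gene, identifiers without a symbol included, ranged from 2360209 in HFD 0 h replicate 3 to 20688063 in HFD 24 h replicate 3. The next lowest total was 9134888, in HFD 0 h replicate 2. Within a group, the Spearman correlation of libraries across genes lay between 0.959 and 0.993, with the lowest value in HFD 0 h. The first principal component held 58.3% of the variance and separated the 24 h from the 0 h libraries. The second held 15.5%, and HFD 0 h replicate 3 stood alone on it, at -82.13, with every other library at -5.55 or higher. A lane tag, lane 8, stood in the labels of the 3 chow 24 h libraries and of HFD 24 h replicate 1, and in no other label. The series title points to the pentose phosphate pathway and to inflammatory responses in hypercholesterolemia, so the comparisons were LPS within each diet, diet at each time, and the difference between the LPS responses of the diets.

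In macrophages of chow-fed mice, inflammatory genes were far higher at 24 h of LPS than at 0 h. Transcripts of Nos2, the inducible nitric oxide synthase (chromosome 11, 78920787 to 78960226, GRCm38.p6), were not counted in any 0 h library and averaged 550.9 ± 91.2 CPM (SD, n = 3) at 24 h, at least 6790-fold higher. The cytokine transcript Il6 was likewise at 0 counts before LPS and at least 36.5-fold higher after it, while Il1b had a log2 fold change of 6.52 ± 0.51 (SE), Tnf of 3.27 ± 0.25 and Ptgs2, which makes prostaglandin precursors, of 4.57 ± 0.41. The interferon-induced genes Cxcl10 and Ifit1 rose with log2 fold changes of 6.22 ± 0.36 and 5.63 ± 0.33, and Hmox1, which breaks down haem, with 1.78 ± 0.15. Abca1 and Abcg1, both cholesterol exporters, went in opposite directions, with 0.92 ± 0.16 and -0.89 ± 0.20. The largest increases by the rule for named genes, besides Nos2, were Serpina3f (at least 1030-fold), Ccl12 (at least 335-fold), Tgtp1 (at least 216-fold) and Cxcl9 (log2 fold change 9.09 ± 0.69). The largest decreases were Slco2b1, an organic anion transporter (691-fold lower, with a counting interval of 124 to 27300 from 1 count at 24 h), Smpd3 (-4.75 ± 0.33), Mamdc2 (-4.68 ± 0.18), Cd28 (-4.27 ± 0.32) and Galnt9 (-4.03 ± 0.32).

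By edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p of 0.05, 3355 of 12638 genes changed with LPS in chow, 1728 up and 1627 down (1499 and 1862 with upper-quartile factors), and 896 and 647 of them had an estimated change of at least 2-fold. Of the 18 genes chosen in advance, 9 rose, 2 fell and 7 did not pass, among them G6pdx, Pgd, Tkt, Il12b and Nqo1, whose adjusted p ran from 0.0653 (G6pdx) to 0.966 (Pgd). All 3 chow 24 h libraries carry the lane tag and no chow 0 h library does, so lane and LPS cannot be told apart within chow. With the tag as a covariate, which leans on HFD 24 h replicate 1, 1509 genes passed. The calls of Abcg1 (log2 fold change -0.69 ± 0.36, adjusted p = 0.259, against -0.89 ± 0.20 without the tag), Ndrg1 (-0.70 ± 0.36, 0.26, against -1.45 ± 0.23) and Fth1 (1.09 ± 0.36, 0.0599, against 1.39 ± 0.19) ended, with smaller folds and larger errors. That of Slco2b1, with 1 count at 24 h, ended too (0.992).

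Gene lists fixed in advance moved together with LPS in chow. All 48 tested interferon-stimulated genes rose, among them Isg15 (log2 fold change 5.70 ± 0.23) and Zbp1, a nucleic acid sensor (4.37 ± 0.17). So did 27 of 29 inflammatory cytokines and chemokines, with the monocyte attractant Ccl2 at 5.21 ± 0.24 and Ccl5 at 4.20 ± 0.16. Of 31 genes of NF-kB feedback and inflammatory effectors 29 rose, with Acod1, which makes itaconate, at 6.35 ± 0.21 and the iron-binding Lcn2 at 7.41 ± 0.31. Of 18 genes of MHC class I presentation 17 rose, including the immunoproteasome subunit Psmb10 (2.92 ± 0.15) and H2-Q7 (4.59 ± 0.17), whose near-identical relatives may share its reads. These 4 lists kept their camera calls when the correlation between genes was estimated, with adjusted p = 0.0215 for the interferon-stimulated genes and 0.0141 for each of the others. Of 26 glycolysis and glucose uptake genes 17 rose and 3 fell, with Pfkfb3 at 1.70 ± 0.12 and the hexokinase Hk2 at 1.46 ± 0.16 (camera adjusted p = 2.54e-05, and adjusted p = 0.114 with an estimated correlation). Of 18 HIF1 and hypoxia targets 10 rose, with Hif1a at 1.60 ± 0.18, and 2 fell, with Ndrg1 at -1.45 ± 0.23 (0.0064, and adjusted p = 0.532 with an estimated correlation). Of 25 NRF2 targets 9 rose, among them the cystine carrier Slc7a11 (1.94 ± 0.28) and the ferritin chain Fth1 (1.39 ± 0.19), and 2 fell (0.0242, and adjusted p = 0.114 with an estimated correlation). Of 23 matrix and fibrosis-associated genes 8 rose, with the protease inhibitor Timp1 at 3.72 ± 0.30 and Tgfbi at 2.63 ± 0.23 (0.00494, and adjusted p = 0.689 with an estimated correlation). Of 17 tested stromal markers outside that list 2 rose and 0 fell, with a median of 0.31. Their mean log2 CPM in replicates 1, 2 and 3 was 4.93, 4.39 and 3.85 at 0 h and 5.23, 4.82 and 4.20 at 24 h.

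Camera called 4 lists lower in the same comparison, those of foam cell genes, lysosome genes, cholesterol biosynthesis and fatty acid oxidation, while LXR targets (adjusted p = 0.879) and fatty acid synthesis (0.471) were not called. Of 20 foam cell and lipid-associated macrophage genes 16 fell, with the receptor Trem2 at -1.45 ± 0.15, and 2 rose, with the scavenger receptor Msr1 at 1.37 ± 0.14 (camera adjusted p = 4.56e-07, and adjusted p = 0.114 with an estimated correlation). Of 33 lysosome genes 15 fell, with the acid lipase Lipa at -1.74 ± 0.17, and 4 rose (0.00156, and adjusted p = 0.576 with an estimated correlation). Of 26 cholesterol biosynthesis genes and SREBP2 targets 7 fell and 0 rose, with the synthase Hmgcs1 at -1.14 ± 0.23 and Lpin1 at -2.27 ± 0.18 (0.00156, and adjusted p = 0.689 with an estimated correlation). Of 29 fatty acid oxidation genes and PPAR targets 8 fell, with Pparg at -2.22 ± 0.17 and the fatty acid carrier Cd36 at -1.11 ± 0.15, and 1 rose (0.0257, and adjusted p = 0.532 with an estimated correlation). With the lane tag as a covariate the calls of the fatty acid oxidation, NRF2 and matrix lists ended, at adjusted p of 0.0578, 0.065 and 0.141. That of the matrix list also ended without chow 0 h replicate 3 (0.0853) or chow 24 h replicate 1 (0.102), and that of the fatty acid oxidation list without chow 24 h replicate 1 (0.0611).

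In macrophages of HFD-fed mice, inflammatory genes were likewise far higher after LPS. Nos2 went from 10 counts over the 3 libraries at 0 h to 212.4 ± 81.3 CPM at 24 h, a log2 fold change of 8.74 ± 0.56. Il6, with 1 count at 0 h, was 23.2-fold higher (counting interval 4 to 930). Il1b (6.64 ± 0.61), Tnf (3.17 ± 0.26), Ptgs2 (3.56 ± 0.43), Cxcl10 (5.74 ± 0.39), Ifit1 (5.91 ± 0.35), Hmox1 (1.25 ± 0.15) and Abca1 (0.85 ± 0.16) rose as well. The largest increases were Serpina3f (at least 659-fold), Cxcl3 (545-fold, counting interval 151 to 4500), Ifit3b (461-fold, counting interval 82.6 to 18200), Nos2 and Ms4a4c (log2 fold change 7.85 ± 0.47). The largest decreases were Slco2b1 (967-fold lower, counting interval 172 to 38300), Pcp4l1 (-5.07 ± 0.40), Cd28 (-4.50 ± 0.31), Mamdc2 (-4.09 ± 0.17) and Cdkn1c, a cell cycle inhibitor (-4.08 ± 0.20). By edgeR's test 3115 genes changed, 1605 up and 1510 down (1392 and 1841 with upper-quartile factors, 1497 and 1511 with limma-voom), with 884 and 652 at an estimated 2-fold or more. Without HFD 24 h replicate 1, the only HFD library with the lane tag, 2920 passed, and the tagged chow 24 h libraries still entered that fit through the filter and the shared spread. Of the 18 genes chosen in advance 10 rose, 1 fell and 7 did not pass, among them Pgd, Tkt, Il12b, Nqo1 and Abcg1, whose adjusted p ran from 0.0634 (Abcg1) to 0.751 (Pgd). Cxcl3 did not pass with limma-voom (adjusted p = 0.158).

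The same 4 inflammatory lists led in HFD: 48 of 48 interferon-stimulated genes rose (Zbp1 5.47 ± 0.19, Isg15 5.82 ± 0.26 and the transcription factor Irf7 4.41 ± 0.19). So did 27 of 29 cytokines and chemokines (Ccl2 5.11 ± 0.24, Ccl5 5.44 ± 0.17). Of 31 NF-kB genes 29 rose (Acod1 7.26 ± 0.22, the lectin receptor Clec4e 6.62 ± 0.28), as did 17 of 18 MHC class I genes (the peptide transporter Tap1 3.74 ± 0.18). With an estimated correlation their camera adjusted p were 0.0223, 0.0149, 0.0157 and 0.0149. Of 26 glycolysis genes 17 rose (Hk2 1.52 ± 0.17, Pfkfb3 1.49 ± 0.13) and 2 fell, and of 18 HIF1 targets 11 rose (Hif1a 1.84 ± 0.19) and 2 fell. Camera called both lists, and with an estimated correlation their adjusted p = 0.139 and 0.375. Of 25 genes of the unfolded protein and integrated stress response 12 rose, among them asparagine synthetase Asns (1.43 ± 0.23) and the chaperone Pdia4 (1.23 ± 0.13), and 3 fell (camera adjusted p = 0.0202, and adjusted p = 0.375 with an estimated correlation). Of 10 MHC class II genes 5 rose, with the class II transactivator Ciita at 1.64 ± 0.32 and H2-DMa at 1.19 ± 0.19 (camera adjusted p = 0.0433, and adjusted p = 0.664 with an estimated correlation). Of 20 foam cell genes 15 fell (Trem2 -1.54 ± 0.15) and 2 rose (Msr1 1.71 ± 0.15). Of 33 lysosome genes 15 fell (Lipa -1.73 ± 0.17, the cathepsin Ctsd -1.10 ± 0.15) and 4 rose, and of 29 fatty acid oxidation genes 9 fell (Pparg -2.05 ± 0.17, Cd36 -1.03 ± 0.15) and 1 rose. Camera called these 3 lists lower, and with an estimated correlation their adjusted p = 0.175, 0.531 and 0.502. The class II call ended without HFD 0 h replicate 1 (adjusted p = 0.0648), HFD 0 h replicate 3 (0.0889) or HFD 24 h replicate 2 (0.115) and with the GC slope as a covariate (0.19). The fatty acid oxidation call (0.0491) ended without HFD 0 h replicate 1 (0.0645) or replicate 2 (0.122), with the lane tag (0.0536) and when only the HFD libraries were fitted (0.0513).

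The LPS responses of the diets, which share no libraries, overlapped: 1327 genes rose in both and 1202 fell in both, against 219 and 194 for independent lists, and 0 went in opposite directions. The log2 fold changes correlated across the 12638 genes with a Pearson r of 0.897 and a Spearman rho of 0.795, where genes are not independent replicates. The plot of LPS fold changes in chow against those in HFD shows each gene.

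**Figure D1:**
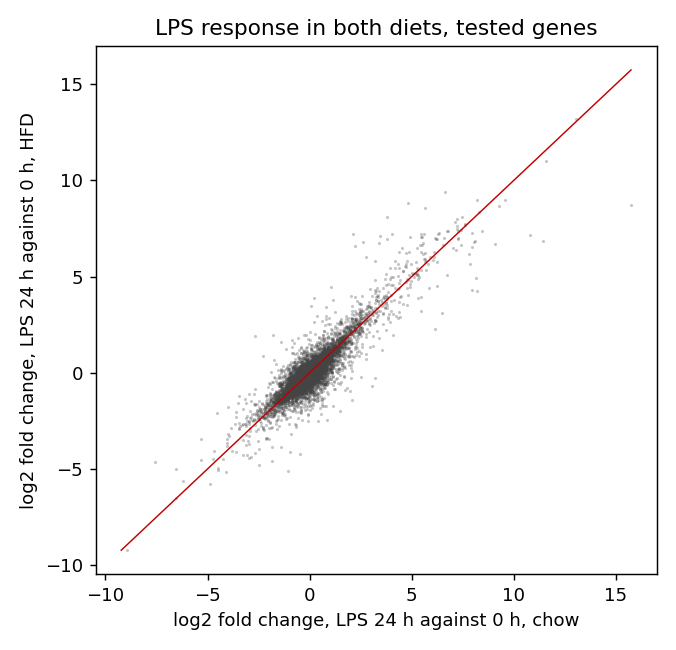
Each point is 1 of the 12638 tested genes, with its fitted log2 fold change at 24 h against 0 h of LPS in chow on the x axis and in HFD on the y axis, and the red line marks equal values. The points lie along the line (Pearson r 0.897 across genes), and fitted values of genes with few counts, which depend on the prior count, are included.

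Before LPS, 11 genes passed edgeR's test between macrophages of HFD-fed and of chow-fed mice. All 11 were lower in HFD, 9 of them by an estimated 2-fold or more, and 5 of them belong to the list of 48 interferon-stimulated genes, whose adjusted p = 0.252 with an estimated correlation. The largest differences were in Ifi27l2a (log2 fold change -1.78 ± 0.27, adjusted p = 0.0128), Rtp4 (-1.68 ± 0.22, 0.00211), Acod1 (-1.50 ± 0.19, 0.00181), the complement factor gene Cfb (-1.42 ± 0.16, 0.000984) and Micall2 (-1.37 ± 0.21, 0.0069). Ccl5 (-1.25 ± 0.15, 0.00134) and the interferon-stimulated genes Irf7 (-1.24 ± 0.17, 0.00291), Zbp1 (-1.12 ± 0.18, 0.0162) and Oas3 (-1.11 ± 0.14, 0.00181) followed. Oasl2 (-0.92 ± 0.17, 0.0471) and Ly6e (-0.79 ± 0.12, 0.0069) complete the 11 and are named after their values were seen. Irf7, for example, went from 189.0 ± 8.2 CPM in chow to 80.2 ± 20.7 in HFD (SD, n = 3). None of the 18 genes chosen in advance passed, with adjusted p from 0.222 (Abcg1, 0.80 ± 0.20) to 0.998. Nos2 had 10 counts in HFD against 0 in chow, with an adjusted p of 0.746. Its bound against 3 counts was 8.74-fold, which covers counting error only and rests on few counts. At an unadjusted p of 0.05, 778 genes passed against 632 by chance. None of these 6 libraries carries the lane tag, which does not show that they were sequenced together. The labels of HFD 0 h replicate 3 and chow 0 h replicate 2 hold the same S number, whose meaning is not given in the sources used here. Without chow 0 h replicate 2 the count of genes was 7, and without HFD 24 h replicate 2, which enters through the filter, the scaling and the shared spread, 25. No gene passed a test for a change above 1.5-fold, with adjusted p from 0.0551 for Acod1, Cfb and Rtp4. Calls ended for Ifi27l2a, Micall2, Ly6e, Zbp1 and Oasl2 on leaving out single libraries: without chow 0 h replicate 1 for Zbp1 (0.159) and Oasl2 (0.171), without replicate 2 for Ifi27l2a (0.0631), Micall2 (0.06), Ly6e (0.0713) and Oasl2 (0.13), and without replicate 3 for Oasl2 (0.148). Without HFD 0 h replicate 1 they ended for Ifi27l2a (0.0771), Ly6e (0.0501), Zbp1 (0.148) and Oasl2 (0.0846), without replicate 2 for Micall2 (0.0739) and Oasl2 (0.153), and without replicate 3 for Ifi27l2a (0.082), Zbp1 (0.0591) and Oasl2 (0.135). Oasl2 was also lost without chow 24 h replicate 1 (0.0535) or 2 (0.0597) and HFD 24 h replicate 1 (0.0628) or 3 (0.06), and limma-voom ended the calls of Ifi27l2a (0.0943), Micall2 (0.193), Zbp1 (0.21) and Oasl2 (0.146).

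**Figure D2:**
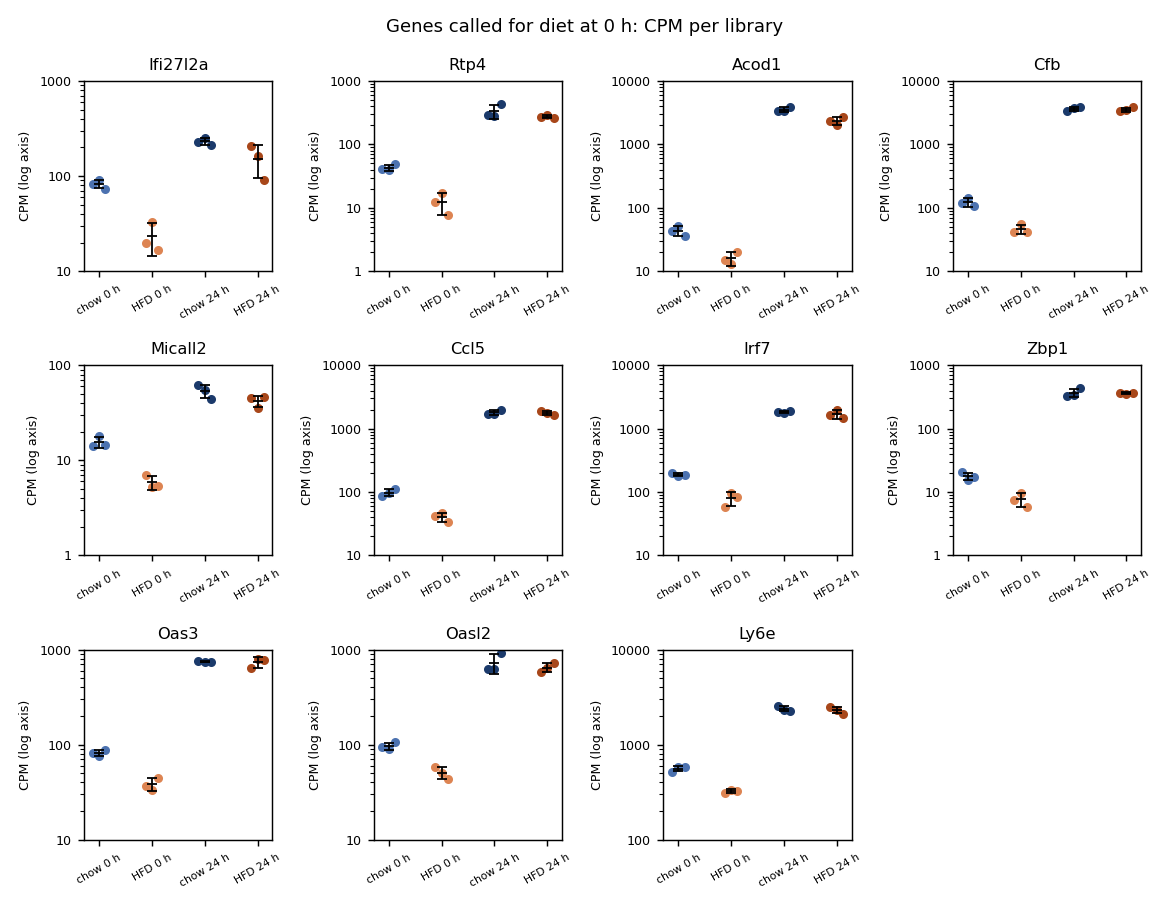
CPM on a log axis of the 11 genes called for diet at 0 h, in each of the 12 libraries, with 3 points per group for the libraries and bars for the mean ± SD. In each panel the HFD 0 h libraries lie below the chow 0 h libraries. The 24 h libraries of both diets lie above all 0 h libraries, except that HFD 24 h replicate 3 (90.9 CPM) lies below chow 0 h replicate 2 (91.9) for Ifi27l2a.

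Among the lists at 0 h, 48 interferon-stimulated genes held 5 that fell in HFD over all genes tested and 15 adjusted over the list alone, with a median log2 fold change of -0.44 (camera adjusted p = 9.4e-17, and adjusted p = 0.252 with an estimated correlation). Genes of cholesterol biosynthesis and SREBP2 targets were lower as a group, with a median of -0.86: 0 of 26 passed over all genes and 21 adjusted over the list alone (2.19e-20, and adjusted p = 0.238 with an estimated correlation). Their smallest adjusted p belonged to Hsd17b7 (-1.35 ± 0.26, 0.069) and Hmgcs1 (-1.15 ± 0.23, 0.0852). Of 13 fatty acid synthesis genes 0 passed over all genes and 7 adjusted over the list alone, with a median of -0.58. Elovl6 was at -1.37 ± 0.27 (0.0723) and Acsl3 at -1.29 ± 0.27 (0.121). The list had a camera adjusted p = 8.71e-08 (adjusted p = 0.238 with an estimated correlation). The matrix list had a median of -0.57, with Timp1 at -1.03 ± 0.31 (0.444) and Tgfbi at -0.81 ± 0.23 (0.348) (5.03e-05, and adjusted p = 0.557 with an estimated correlation), and its call ended without chow 0 h replicate 1 (0.0741). The NF-kB list, with Marco at -1.36 ± 0.27 (0.0733), was called lower (0.00137, and adjusted p = 0.498 with an estimated correlation), but not without HFD 0 h replicate 1 (0.161). In all, 13 of 32 lists were called, 11 lower and 2 higher in HFD, and with an estimated correlation 0 were. The count of lists called was 7 without chow 0 h replicate 1 and 6 without HFD 0 h replicate 1.

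After 24 h of LPS, 1 gene passed between the diets: Mamdc2 (chromosome 19, 23302609 to 23448497) was at 37.1 ± 1.8 CPM in HFD and 15.9 ± 2.4 in chow (SD, n = 3). Its log2 fold change was 1.22 ± 0.16, with an edgeR adjusted p of 0.0138. None of the 18 genes chosen in advance passed. Nos2 had -1.37 ± 0.31 (adjusted p = 0.297), Il6 -1.42 ± 0.45 (0.503), Cxcl10 -0.97 ± 0.27 (0.384), Il1b -0.52 ± 0.35 (0.764), Ptgs2 -0.58 ± 0.32 (0.688), Tnf -0.31 ± 0.22 (0.789), Hmox1 -0.68 ± 0.15 (0.172) and Abcg1 1.17 ± 0.20 (0.0849). At an unadjusted p of 0.05, 993 genes passed against 632 by chance, and DESeq2 called 43. The Mamdc2 call ended without chow 24 h replicate 1 (1.11 ± 0.18, adjusted p = 0.183), chow 24 h replicate 2 (1.21 ± 0.19, 0.158) or HFD 24 h replicate 2 (1.23 ± 0.18, 0.0563). It also ended with the lane tag as a covariate (1.30 ± 0.22, 0.0882), with only these 6 libraries (1.21 ± 0.16, 0.0809) and in a test for a change above 1.5-fold (1). With the tag the fold was not smaller and its error was larger. The fits without a library and of the 6 libraries rest on fewer libraries, while the 1.5-fold test uses all 12 and asks for a larger change. The tag marks all 3 chow 24 h libraries and 1 of HFD, so a fit within untagged libraries was not possible. With the tag as a covariate the difference compares HFD 24 h replicate 1 alone with the chow 24 h libraries. The count of genes was 4 without HFD 0 h replicate 3, 3 without HFD 24 h replicate 1, 2 without chow 24 h replicate 3 or HFD 24 h replicate 3, and 0 without each of the 3 libraries that ended the Mamdc2 call.

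At 24 h 16 of 32 lists were called by camera, 11 lower and 5 higher in HFD, and 1 of them with an estimated correlation. That list was the NRF2 targets, of which 0 of 25 passed over all genes and 4 adjusted over the list alone. Their median was -0.19, with the peroxiredoxin Prdx1 at -0.74 ± 0.14 (adjusted p = 0.122), and the list had a camera adjusted p = 1.14e-05 (adjusted p = 0.0214 with an estimated correlation). Inflammatory cytokines and chemokines were lower as a group, with a median of -0.52 over 29 genes and Ccl7 at -0.84 ± 0.21 (0.297) (2.33e-07, and adjusted p = 0.184 with an estimated correlation). Lower as well were the matrix list (median -0.83, Timp1 -1.34 ± 0.27, fibronectin Fn1 -0.83 ± 0.27, 3.35e-09) and the cholesterol biosynthesis list (median -0.40, Sqle -0.81 ± 0.27, 4.74e-09), both with adjusted p = 0.521 with an estimated correlation. The mean log2 CPM of the cholesterol list in replicates 1, 2 and 3 was 5.671, 5.724 and 5.44 in chow 24 h and 5.424, 4.589 and 5.377 in HFD 24 h, with replicate 2 of HFD far lowest. Interferon-stimulated genes had a median of -0.16, with Rsad2 at -0.84 ± 0.25 and Oasl1 at -0.72 ± 0.17 (0.000436, and adjusted p = 0.521 with an estimated correlation). Immediate early and heat shock genes had a median of -0.10, with Hspa1a at -1.57 ± 0.39 (0.0092, and adjusted p = 0.521 with an estimated correlation). LXR targets and cholesterol efflux genes were higher in HFD, with a median of 0.13 and the lipid transfer protein Pltp at 0.68 ± 0.18 (0.0092, and adjusted p = 0.521 with an estimated correlation). Lysosome genes were higher as well (median 0.14, 0.000468, and adjusted p = 0.521 with an estimated correlation). With the lane tag as a covariate 10 lists were called, and the calls of the cholesterol list (0.0862) and of the immediate early list (0.313) ended. In that fit HFD 24 h replicate 1 alone stands for HFD. The call of the interferon-stimulated genes ended without chow 24 h replicate 3 (0.377) or HFD 24 h replicate 1 (0.775) and with sample quality weights (0.325). That of the LXR targets ended without chow 24 h replicate 3 (0.0539) or HFD 24 h replicate 1 (0.177) and with quality weights (0.0523). That of the immediate early genes ended without chow 24 h replicate 1 (0.0718) or replicate 2 (0.102), without both chow replicate 1 libraries (0.0786) and with the GC slope as a covariate (0.147). Without chow 24 h replicate 2 the count of lists was 9.

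The pentose phosphate pathway, which turns glucose 6-phosphate into NADPH and ribose 5-phosphate, held no gene that passed between the diets. G6pdx, its entry enzyme (chromosome X, 74409483 to 74428880), had a log2 fold change HFD against chow of -0.16 ± 0.19 at 0 h and -0.09 ± 0.19 at 24 h. Pgd (chromosome 4, 149149991 to 149166705) had -0.24 ± 0.14 and -0.31 ± 0.14, and Tkt (chromosome 14, 30549131 to 30574724) -0.38 ± 0.18 and -0.22 ± 0.18. Taldo1 (chromosome 7, 141392160 to 141402976) had -0.03 ± 0.15 and -0.19 ± 0.15. The adjusted p of these 4 genes was at least 0.801 at 0 h and 0.63 at 24 h. The 15 tested members gave a camera adjusted p of 0.985 at 0 h, where median (-0.03), mean (0.04) and test (up) differed in sign, and 0.759 at 24 h. In simulated data with 50 genes changed 2-fold, the test recovered 74% of them for diet at 0 h and 78% at 24 h, and 24% and 28% of 50 genes changed 1.5-fold, so most differences of that size would not have been detected. The simulated counts were independent between genes, so recovery in the real libraries may be lower. With LPS in chow, Rpe (0.62 ± 0.14), Rpia (0.61 ± 0.21) and H6pd (0.42 ± 0.14) rose and Taldo1 fell (-0.86 ± 0.16), while G6pdx (0.50 ± 0.19, adjusted p = 0.0653), Tkt (-0.41 ± 0.18, 0.104) and Pgd (-0.01 ± 0.14, 0.966) did not pass. In HFD, Rpe (0.82 ± 0.14), H6pd (0.41 ± 0.14) and G6pdx (0.57 ± 0.19, 0.0365) rose and Taldo1 fell (-1.02 ± 0.16). As a list the pathway was not called with LPS in chow (0.692) or HFD (0.534) by camera, and fry, which asks whether its genes move on balance one way, gave adjusted p of 0.0438 and 0.00367. The Rpia call ended without replicate 2 or 3 of chow at either time (adjusted p from 0.0631 to 0.177), and that of H6pd in chow without any chow library but 24 h replicate 3 (0.0643 to 0.116). In HFD the H6pd call ended without any HFD library or chow 0 h replicate 2 (0.0509 to 0.0795), and that of G6pdx without HFD 0 h replicate 2 or 3, HFD 24 h replicate 1 or 3, or chow 0 h replicate 2 (0.0504 to 0.117). With the lane tag as a covariate the calls of Rpe (0.74 ± 0.24, adjusted p = 0.0584), Rpia (0.39 ± 0.37, 0.595) and H6pd (0.39 ± 0.25, 0.392) in chow ended. So did those of H6pd (0.40 ± 0.15, 0.0773) and G6pdx (0.57 ± 0.22, 0.0747) in HFD. Each of these 5 errors was larger than without the tag. Between the diets, G6pdx turned direction without HFD 0 h replicate 3 at 0 h (0.038) and without chow 24 h replicate 3 at 24 h (0.054), and Taldo1 at 0 h without HFD 0 h replicate 2 (0.099).

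**Figure D3:**
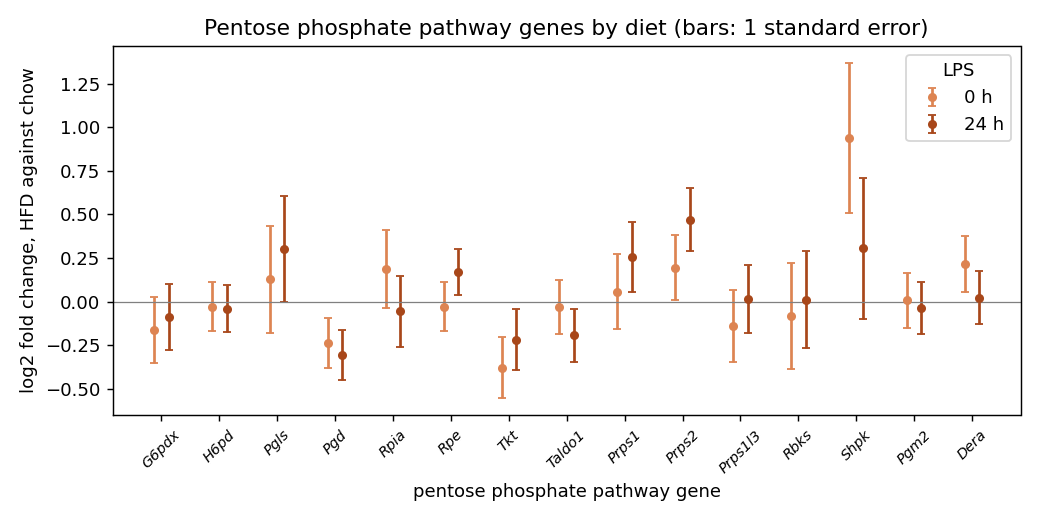
Log2 fold change HFD against chow of the 15 tested pentose phosphate pathway genes at 0 h and at 24 h of LPS, with bars of 1 SE on either side. For G6pdx, Pgd, Tkt and Taldo1 the values lie between -0.38 and -0.03.

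For the difference between the LPS responses of the diets, the interaction, 0 genes passed edgeR's test, 297 had an unadjusted p under 0.05 against 632 by chance, and DESeq2 called 9. All 18 genes chosen in advance had an adjusted p of 1. G6pdx differed by 0.08 ± 0.27 on the log2 scale, Tnf by -0.09 ± 0.34, Il1b by 0.12 ± 0.95 and Hmox1 by -0.53 ± 0.21. Among the interferon-stimulated genes that were lower in HFD before LPS, Rtp4 was at 1.39 ± 0.29, Irf7 at 1.12 ± 0.23, Zbp1 at 1.11 ± 0.24 (adjusted p = 0.395 each) and Oas3 at 1.09 ± 0.19 (0.133). The same 0 h libraries enter the interaction with the opposite sign, so a positive value is partly built in for genes picked as lower there. Camera called 5 of 32 lists, all with a positive difference, the log2 fold change with LPS in HFD minus that in chow, and with an estimated correlation each had an adjusted p of 0.834. They were the interferon-stimulated genes (median 0.28), cholesterol biosynthesis (median 0.50, Hsd17b7 1.12 ± 0.35) and fatty acid synthesis (median 0.33, Acsl3 1.11 ± 0.37, Elovl6 0.85 ± 0.36). For cholesterol biosynthesis the median LPS change was -0.53 in chow and -0.04 in HFD, where the list was not called (adjusted p = 0.452), and for fatty acid synthesis it was -0.27 and 0.18. The others were MHC class II (median 0.36, H2-Aa 0.49 ± 0.35, H2-DMb1 0.32 ± 0.25) and the unfolded protein response (median 0.14, Asns 0.71 ± 0.31, Pdia4 0.39 ± 0.18). With the lane tag as a covariate the interferon list turned direction (adjusted p = 0.785), and without HFD 0 h replicate 2 the cholesterol and fatty acid calls ended (0.166 and 0.0944). With the tag, HFD 24 h replicate 1 alone stands for HFD at 24 h. The count of genes was 3 without chow 24 h replicate 3 or HFD 0 h replicate 2. The count of lists was 3 without HFD 0 h replicate 1 and 9 without HFD 0 h replicate 3, HFD 24 h replicate 1 or HFD 24 h replicate 3.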

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

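The tests for carry-over of LPS-treated RNA and for the shallow library, and the fits with the GC slope or without both chow replicate 1 libraries, were chosen after the result was seen.

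For 5 gene lists the LPS response differed between the diets by the test of the interaction, with camera adjusted p of 9.03e-06 for interferon-stimulated genes, 5.44e-05 for cholesterol biosynthesis, 0.0049 for fatty acid synthesis, 0.018 for MHC class II and 0.0232 for the unfolded protein response. With an estimated correlation between genes the adjusted p was 0.834 for each. In the cholesterol list the difference, HFD minus chow, was above 0 for 25 of 26 genes, Hmgcs1 among them (0.70 ± 0.32), and 0 passed singly. The median LPS change of this list was -0.53 in chow and -0.04 in HFD, where it was not called (0.452). A list lower in HFD at 0 h enters the interaction with the opposite sign through the same 0 h libraries, so the interferon, cholesterol, fatty acid and unfolded protein results are not independent of the diet comparison at 0 h. With the lane tag as a covariate the interferon list turned direction (0.785), and the class II and unfolded protein calls ended (0.326 and 0.0695). In that fit HFD 24 h replicate 1 alone stands for HFD at 24 h. The fatty acid call also ended without chow 24 h replicate 3 (0.0964). The class II call ended without chow 0 h replicate 3 (0.144), chow 24 h replicate 1 (0.165) or 2 (0.0705), HFD 0 h replicate 1 (0.11) or 3 (0.101) or HFD 24 h replicate 2 (0.368), without both chow replicate 1 libraries (0.184) and with the GC slope (0.14). The unfolded protein call ended without chow 0 h replicate 1 (0.162) or 2 (0.0875), chow 24 h replicate 3 (0.165), HFD 0 h replicate 1 (0.11) or 2 (0.103) or HFD 24 h replicate 2 (0.0571), and without both chow replicate 1 libraries (0.103). Among 100 splits of the libraries, 68 gave at least the 5 lists called here, up to 16, so chance cannot be excluded for the lists. With 0 genes passing, all 100 splits reach that count whatever the data, so the count of genes tests nothing. The highest other split gave 422 genes, which points to a structure of the samples.

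The lower interferon genes in HFD at 0 h could come from LPS-treated RNA in the chow 0 h libraries. The 11 called genes would need a median share of 6.18% of chow 24 h RNA there, which predicts 1259 Nos2 counts (lower 95% limit 1190), and 0 were counted, which argues against it. The shallow HFD 0 h replicate 3 as the whole source is argued against by the 8 of 11 genes still called without it. Marker lists of monocytes (median -0.47, camera adjusted p = 0.00872, and 0.238 with an estimated correlation) and dendritic cells (-0.38, 0.0133, and 0.498) were also called lower in HFD at 0 h, and whether a different share of such cells accounts for the interferon genes was not tested. Diet itself, and differences between the mice or their handling that go with diet, were not tested either, and all of these stay open.

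For the other comparisons, fits of the 6 libraries alone allow 10 splits, too few for a share under 0.05. LPS in chow gave 3952 genes against 0 in the highest other split and 13 lists against 13. LPS in HFD gave 2489 genes against 0 and 12 lists against 15. Diet at 0 h gave 12 genes against 0 and 13 lists against 13, and diet at 24 h gave 0 genes against 134 and 17 lists against 13. The split with 134 genes set chow 24 h replicates 1 and 2 and HFD 24 h replicate 1 against the other 3 libraries, which points to a structure of the samples other than diet. Those 3 libraries had slopes of log2 CPM on GC content of -0.193, -0.287 and -0.102, and the other 3 of -3.817, -3.037 and -3.635.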

How the results depend on the processing

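The fits with summed isoforms, sample quality weights, both chow replicate 1 libraries left out, and the GC slope as a covariate were chosen after the data were seen. Of 48 called named genes for LPS in chow 39 kept their call and direction under every alternative run, and of 43 for LPS in HFD 38 did. None of the 11 called at 0 h, nor the 1 at 24 h, did so, since 0 passed the test for a change above 1.5-fold. At 0 h, Acod1, Cfb, Rtp4, Ccl5, Irf7 and Oas3 lost their call in that test alone, which asks for a larger change. Over all alternatives 7 of 1431 values turned direction for LPS in chow, 1 of 1295 for LPS in HFD, 8 of 887 for diet at 0 h, 5 of 701 for diet at 24 h and 32 of 728 for the interaction, all in genes that had not passed. The random-effect block and DESeq2 were run for genes only, the 1.5-fold test likewise, and the interaction cannot be fitted on fewer than 4 groups. Depth limits HFD 0 h most, where replicate 3 holds 2360209 counts.

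Besides those named with the results, calls ended with upper-quartile factors for Rpia (0.0753) and H6pd (0.0666) in chow and H6pd (0.0939) and G6pdx (0.0507) in HFD. With only the groups compared they ended for Rpia (0.0587), for H6pd (0.0761) and G6pdx (0.065) in HFD, and at 0 h for Micall2 (0.0626) and Zbp1 (0.153). Oasl2 was also lost with median-ratio factors (0.0562), the lane tag (0.0549) and summed isoforms (0.067), and Rpia with summed isoforms (0.0531). Without both chow replicate 1 libraries calls ended for H6pd (0.287) and Rpe (0.0593) in chow, H6pd (0.0635) and G6pdx (0.0538) in HFD, Ifi27l2a (0.0709), Zbp1 (0.166) and Oasl2 (0.176) at 0 h and Mamdc2 (0.162) at 24 h. Quality weights ended those of G6pdx (0.0615) and Cxcl3 (0.21) in HFD and Zbp1 (0.0557) at 0 h, and the GC slope those of G6pdx in HFD (log2 fold change 0.39, adjusted p = 0.11) and Ifi27l2a (0.0654). The test above 1.5-fold ended those of Abcg1 (0.148), Abca1 (0.0619), Taldo1 (0.107), Rpe (0.724), Rpia (0.827) and H6pd (1) in chow and of Abca1 (0.139), Rpe (0.12), G6pdx (0.918) and H6pd (1) in HFD.

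List calls not given with the results ended as follows. Without both chow replicate 1 libraries they ended for fatty acid oxidation with LPS in chow (0.0501), at 0 h for fatty acid oxidation (0.0601), the unfolded protein response (0.193), alternative activation (0.126), lysosome genes (0.0822) and dendritic markers (0.0601), and at 24 h for fatty acid synthesis (0.0593), class II (0.269) and dendritic markers (0.0786). With the GC slope they ended at 0 h for alternative activation (0.053) and at 24 h for NF-kB genes (0.0871), fatty acid synthesis (0.105), class II (0.199), foam cell genes (0.111), ribosomal proteins (0.0621) and dendritic markers (0.054). Without a filter they ended at 0 h for fatty acid oxidation (0.0605) and for alternative activation, monocyte and dendritic markers (0.0502 each), and at 24 h for dendritic markers (0.0574). With only the groups compared they ended for alternative activation at 0 h (0.098) and ribosomal proteins at 24 h (0.05), and with summed isoforms for alternative activation at 0 h (0.0552) and dendritic markers at 24 h (0.0826).

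The count of genes for diet at 0 h, 11 as reported, was 23 without a filter, 66 with DESeq2, 47 with quality weights and 0 above 1.5-fold. Not all of these were lower in HFD: DESeq2 had 9 higher and 57 lower, and quality weights 13 higher and 34 lower. For diet at 24 h it was 10 without a filter, 43 with DESeq2, 10 with limma-voom, 58 with quality weights, 9 with the GC slope, and 0 with the lane tag, above 1.5-fold, with only the groups compared and without both chow replicate 1 libraries. For the interaction it was 3 without a filter, 9 with DESeq2, 5 with quality weights and 2 with the GC slope. LPS in chow gave 1509 genes with the lane tag, 5440 with quality weights and 1355 above 1.5-fold, where LPS in HFD gave 1325. Fewer pass above 1.5-fold by construction, and for the rest the cause was not tested. Leaving out each library gave 2532 to 3821 genes for LPS in chow, 2519 to 3372 for LPS in HFD, 7 to 25 for diet at 0 h, 0 to 4 for diet at 24 h and 0 to 3 for the interaction. It gave 6 to 14 lists for diet at 0 h, 9 to 16 for diet at 24 h and 3 to 9 for the interaction. With an estimated correlation 4, 4, 0, 1 and 0 lists were called for LPS in chow, LPS in HFD, diet at 0 h, diet at 24 h and the interaction. Fry called 17 for LPS in HFD, 2 for diet at 0 h, 1 for diet at 24 h and 0 for the interaction. The lane tag left 10 and the GC slope 9 lists at 24 h, quality weights gave 13 for the interaction, and without both chow replicate 1 libraries there were 7 at 0 h and 3 for the interaction.

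The pentose phosphate pathway list passed fry for LPS in chow (adjusted p = 0.0438) and HFD (0.00367). At 0 h its direction turned without a filter (0.996), with limma-voom (0.956), with only the groups compared (0.979), with fry (0.603), with quality weights (0.923) and with the GC slope (0.913), and for the interaction with quality weights (0.993). It also turned at 0 h without chow 0 h replicate 2 (0.951), chow 24 h replicate 2 (0.988) or 3 (0.958), HFD 0 h replicate 1 (0.915) or HFD 24 h replicate 1 (0.997), and for the interaction without HFD 0 h replicate 2 (0.854). Leaving out each library gave 0.87 to 0.998 at 0 h and 0.758 to 0.993 for the interaction.

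Log2 fold changes that turned direction, none of them called and the cause not tested, were as follows. For LPS in chow, Pgd was 0.011 without a filter, 0.11 with quality weights and 0.044 with the GC slope (-0.12 to 0.15 leaving out each library). For LPS in HFD, Pgd was 0.085 with the GC slope. For diet at 0 h, Taldo1 was 0.002 without both chow replicate 1 libraries (-0.21 to 0.099 leaving out each library), G6pdx ranged from -0.41 to 0.038, Tnf from -0.36 to 0.069 and Il12b from -5.87 to 0.41. For diet at 24 h, Tkt was 0.005 with the lane tag, Nqo1 was 0.015 with quality weights (-0.37 to 0.025), G6pdx ranged from -0.16 to 0.054 and Il12b from -1.17 to 0.18. For the interaction, Il1b was -0.20 with limma-voom and -0.12 with quality weights (-0.21 to 0.51), Il12b was 0.73 with limma-voom and 1.08 with quality weights (-0.87 to 5.41), Tnf was 0.082 with the lane tag and 0.03 with quality weights (-0.37 to 0.10), Ifit1 was -0.39 with the lane tag (-0.023 to 0.56), G6pdx was -0.004 (-0.12 to 0.33) and Pgd 0.041 (-0.21 to 0.054) with the GC slope. There Tkt ranged from -0.043 to 0.32, Taldo1 from -0.29 to 0.014 and Abca1 from -0.23 to 0.19. The extremes of Il12b arise where the remaining HFD 0 h libraries hold 0 counts, so their size depends on the prior count.

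The labels hold a number shared across LPS times, which differs between the diets, and diets share replicate numbers 1 to 3. Deviations of libraries with the same label number from their group means correlated at 0.301, 0.091 and 0.346 in chow and 0.055, 0.263 and 0.03 in HFD, so not every pair was over 0.1, and not every library correlated best with its own number. Between the diets, those with the same replicate number correlated at -0.139, -0.012 and -0.048 at 0 h and 0.17, -0.11 and 0.213 at 24 h. Whether these libraries share more than a number cannot be told from such values. The replicate block was the label number for LPS and the interaction, and for diet the replicate number, which pairs libraries of different diets. With it, 3711 genes passed for LPS in chow, 3395 for LPS in HFD, 18 for diet at 0 h, 1 for diet at 24 h and 4 for the interaction, and the fatty acid oxidation call in HFD ended (0.0585). The label number as a random effect gave 4151, 3479, 8, 14 and 3, and the calls of Cxcl3 in HFD (0.164) and of Ifi27l2a (0.059), Micall2 (0.156), Zbp1 (0.187) and Oasl2 (0.107) at 0 h ended. In the interaction Il1b was -0.096 with the block and -0.27 with the random effect, where Il12b was 0.72.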

Other observations

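The test of the lane tag on the matrix genes was chosen after the result was seen, as was the fit without both chow replicate 1 libraries.

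Markers of other cells of the peritoneal cavity moved in part with LPS, and whether this reflects such cells or expression in the macrophages was not tested. Ly6c2, a marker of monocytes, went from 2.45 ± 1.02 CPM to 125.7 ± 63.3 (SD, n = 3) in chow (log2 fold change 5.67 ± 0.43, edgeR adjusted p = 2.85e-07), and Siglecf, carried by eosinophils, fell from 21.5 ± 1.2 to 3.89 ± 0.66 (-2.46 ± 0.23, 3.18e-07). Their lists were not called: of 13 monocyte and small peritoneal macrophage markers 6 rose and 4 fell (camera adjusted p = 0.692), and of 10 mast cell and eosinophil markers 1 rose and 1 fell (0.895). Of 9 mesothelial and epithelial markers 2 fell in chow (median -1.37, camera adjusted p = 0.167) and 3 in HFD (-0.87, 0.0826), and camera called this list lower in 4 and 12 of 25 settings. Of 7 neutrophil markers 3 rose and 1 fell in chow (median 0.34, 0.236) and 3 rose in HFD (0.74, 0.186), called in 1 and 0 of 25 settings. Fry, which does not compare a list with other genes, gave adjusted p of 0.0221 and 0.0124 for the mesothelial and 0.00233 and 0.00104 for the neutrophil markers. Lcn2, the neutrophil marker with the largest increase in chow, is also in the NF-kB list. Of 21 large peritoneal macrophage markers 6 rose and 5 fell in chow.

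Other lists were called between the diets by camera with 0 members passing, apart from Ccl5 among the cytokines at 0 h. At 0 h they were lower in HFD for cytokines (median log2 fold change -0.30, adjusted p = 0.00649), monocyte markers (-0.47, 0.00872), dendritic cell markers (-0.38, 0.0133), NRF2 targets (-0.11, 0.0347), the unfolded protein response (-0.06, 0.0427) and alternative activation (-0.28, 0.0427), and higher for lysosome genes (0.13, 0.0048) and fatty acid oxidation (0.11, 0.0343). At 24 h they were lower for the respiratory chain (-0.18, 6.11e-05), ribosomal proteins (-0.13, 0.0289), fatty acid synthesis (-0.18, 0.0289), NF-kB genes (-0.14, 0.0369) and dendritic cell markers (-0.23, 0.0369), and higher for fatty acid oxidation (0.10, 0.00883), foam cell genes (0.07, 0.0289) and MHC class II (0.23, 0.0369). With an estimated correlation the adjusted p of these lists was at least 0.238 at 0 h and 0.521 at 24 h. With the lane tag as a covariate the respiratory chain and ribosomal lists turned direction at 24 h (0.0749 and 0.0712). It also ended the fatty acid synthesis (0.448), NF-kB (0.0846), dendritic (0.259) and class II (0.562) calls there.

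Most of these calls ended when single libraries were left out, and those fits rest on fewer libraries. At 0 h, calls ended without chow 0 h replicate 1 for dendritic markers (0.0595), the unfolded protein response (0.219), alternative activation (0.11), lysosome genes (0.0595) and fatty acid oxidation (0.0595). They ended without chow 0 h replicate 2 for the unfolded protein response (0.104) and without replicate 3 for NRF2 targets (0.155). Without HFD 0 h replicate 1 they ended for dendritic markers (0.134), NRF2 targets (0.138), the unfolded protein response (0.161), alternative activation (0.316), lysosome genes (0.148) and fatty acid oxidation (0.138). Without replicate 2 they ended for NRF2 targets (0.159), the unfolded protein response (0.127), lysosome genes (0.0687) and fatty acid oxidation (0.235), and without replicate 3 for monocyte markers (0.0609), dendritic markers (0.108) and alternative activation (0.127). Through the filter, the scaling and the shared spread, alternative activation was also lost without chow 24 h replicate 1 (0.053) or 3 (0.0554) or HFD 24 h replicate 2 (0.0536). So was the unfolded protein response without the last of these (0.0536). At 24 h, calls ended without chow 24 h replicate 1 for fatty acid synthesis (0.0504), dendritic markers (0.102) and class II (0.253). Without replicate 2 they ended for ribosomal proteins (0.143), fatty acid synthesis (0.248), NF-kB genes (0.139), dendritic markers (0.0882), foam cell genes (0.102) and class II (0.144), and without replicate 3 for ribosomal proteins (0.0601) and NF-kB genes (0.636). Without HFD 24 h replicate 1 they ended for NF-kB genes (0.158), dendritic markers (0.0624) and foam cell genes (0.207). Without replicate 2 they ended for ribosomal proteins (0.0903), fatty acid synthesis (0.251), NF-kB genes (0.55), dendritic markers (0.113) and class II (0.55), and without replicate 3 for the respiratory chain (0.4) and ribosomal proteins (0.765). Dendritic markers were lost without HFD 0 h replicate 3 as well (0.0842). The cytokine call at 0 h and that of fatty acid oxidation at 24 h held without each of the 12 libraries in turn.

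Across genes the diet differences at 0 h and 24 h correlated with a Pearson r of 0.318 and a Spearman rho of 0.319, and genes are not independent replicates. The label numbers recur at both times, and whether they mark the same mice is not given in the sources used here, so the differences are not known to be independent.

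Camera called the matrix list lower in HFD at both times, with medians of -0.574 and -0.831, 0 of 23 genes passing at either time and adjusted p = 0.557 and 0.521 with an estimated correlation, and a smaller share of stromal cells in the HFD libraries is a candidate explanation. Of 20 stromal markers outside the matrix list, chosen without their values, 17 were tested and 17 were lower at 24 h and 15 at 0 h, with medians of -0.784 and -0.666, as that explanation needs. Prrx1, Cdh11 and Ddr2, which do not encode matrix proteins, had -0.782, -0.769 and -0.698 at 24 h. Col5a2, Col6a2, Col6a3, Fbn1, Fbln2 and others do encode them, so a fall of matrix genes in any cell would lower many of the 17 markers too. Among the abundant ones at 24 h in chow replicates 1, 2 and 3 and HFD replicates 1, 2 and 3, Cald1 was at 138.4, 100.1, 86.1, 58.2, 55.5 and 74.8 CPM and Fstl1 at 181.3, 158.7, 110.3, 141.4, 117.6 and 141.5, and how many of the markers macrophages also express was not tested. With the lane tag as a covariate the median of the matrix list at 24 h was -0.794. That fit compares HFD 24 h replicate 1, the only tagged HFD library, with the tagged chow 24 h libraries. The lower median is thus present without a difference in lane, but in 1 HFD library, so the part of the sequencing lane is not decided. The libraries of the diets overlapped in the mean log2 CPM of the list (chow 0 h replicate 3 at 5.563 and HFD 0 h replicate 3 at 5.851, chow 24 h replicate 3 at 6.242 and HFD 24 h replicate 1 at 6.353), without both chow replicate 1 libraries, in which most of these markers were highest, the call ended at 0 h (0.0607), and lower expression in the macrophages themselves, which was not tested, stays open.

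HFD 0 h replicate 3 stood apart, with a distance to its group 1.353 times the largest of any other library over 8259 genes. With every library thinned to 2360209 counts the ratio was 1.184, so low depth may account for part of it, and the value lies between the limits set for either answer. Its deviation correlated across genes with GC content at a Spearman rho of 0.447, but HFD 24 h replicate 1 (0.613) and chow 24 h replicate 3 (-0.524) had larger values. Its slope of log2 CPM on GC content was 2.355, against -0.949 and -1.678 in HFD 0 h replicates 1 and 2, and every other library had a negative slope. GC content stays open. Transcript length, with a rho of 0.081, is argued against. Its label holds the same S number as that of chow 0 h replicate 2, and whether it was prepared or sequenced apart was not tested. No biological explanation was tested for this library.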
